A study of Mus musculus with 4 samples.

How the data were processed

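Chromatin immunoprecipitation followed by sequencing was analysed from 4 libraries of RAW264.7 cells. Ipr1 and control cells each had 1 streptavidin library, Ipr1 cells had 1 anti-Flag library, and control cells had 1 library titled IgG. Per the labels, chromatin was prepared with an enzymatic kit and the molecule is genomic DNA, although the same label text speaks of RNA libraries. Reads were aligned with Bowtie 0.12.8 to mm10, per the submitters' processing notes. The peak caller's version, its settings and the annotation version are not given in the sources used here. The authors called peaks once for each isolation, 1 Ipr1 library against 1 control library, so the 2 deposited lists are comparisons and hold no values for single libraries.

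Each deposited peak has a score, which per the file headers is 10 times the negative log10 of the peak p. The authors' tag counts are whole numbers of tags in the peak. The deposited signal at each summit is the pileup height. The deposited fold enrichment is a ratio over a background set by the authors' caller, and the deposited false discovery rate is a percent. The ratio of fold to summit height was at its upper limit, within 1%, for 72.2% of streptavidin peaks and 55.0% of anti-Flag peaks, read from the values. Scores, folds, false discovery rates and ranks were used to describe, rank and filter peaks within a list, and never to compare strength between the lists. The deposited gene ontology tables were not used here.

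Positions are 1-based mm10 coordinates. Comparisons used chromosomes 1 to 19 and X, which left out 1 mitochondrial streptavidin peak and, for anti-Flag, 2 mitochondrial peaks and 1 on chromosome Y. Gene extents came from the RefSeq annotation of GRCm38.p6, the assembly that mm10 names, limited to 26123 genes with a curated transcript. Of 6659 transcripts in the authors' tables, 6639 matched a gene there by identifier, and 99.1% of these lay within 2 kb of that gene's bounds. The copy of that annotation used here gives no strand. TSS and 3' ends therefore came from the 6659 transcripts in the authors' tables, and random placements were compared at either gene end, which departs from the planned comparison at the TSS. Of genes with a summit within 5 kb of either end, the authors' tables held 86.4% for streptavidin and 86.7% for anti-Flag, and at 10 kb 64.3% and 67.5%, so TSS shares are lower bounds, and transcripts far from any peak are not among those compared at their 2 ends. The authors' column of distances to the TSS was not used, because for all 1186 of its minus-strand entries checked the peak lay within the stated window of the lower coordinate, which is the 3' end, and for 17.9% within that window of the higher one. No genome sequence was used here, so base composition, motifs and unique alignment were not analysed here.

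The number of peaks near a gene end or in a gene body was given as a percent with a 95% Wilson interval and set beside 1000 random placements of each peak within its chromosome. Chromosome extents ran from the lowest to the highest coordinate of a peak or gene. Peaks per Mb carry exact Poisson intervals. Peaks were shared when they had at least 1 bp in common, and the streptavidin list, the shorter, was placed 1000 times. Medians of shared and unshared peaks were compared with 2000 bootstrap draws over peaks. Gene list counts took genes with a summit within 5 kb of a TSS and were ranked among 10000 random lists matched on gene span in 10 classes. Neighbouring genes can share a peak, so such percentiles are more extreme than independent genes would give. With 1 library per arm no test across replicates was possible, and percentiles describe these libraries only.

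The groups, tests, 25 gene lists, most other settings and the rule for named genes were fixed before the data were examined. The rule took the gene nearest to the 15 highest-scored peaks of each list, the 20 genes with a summit within 5 kb of a TSS in both lists by the worse of their ranks, up to 4 members of each gene list with the highest-scored such summit, and Sp110, Sp100 and Sp140. The comparison of the TSS with the 3' end, the segments of 5 Mb and 1 Mb, and the moves of 5 to 500 kb were chosen after the lists had been seen. The result of 1 gene list is left out of the text because it concerns an item withheld for evaluation. Alternatives covered score, fold and false discovery rate limits, window sizes, the point that stands for a peak, the rule that ties peaks to genes, matching, the overlap needed and the chance model.

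The procedures were tested on simulated data. Distances and gene bodies were right at all 500 positions tried. In 20 draws with 80 streptavidin peaks laid on anti-Flag peaks, a mean excess of 77.3 was found, and all 20 draws lay above their placements. Without planted peaks the mean excess was -2.25 and 0 of 20 draws lay outside the central 95%. These draws were made with the same random placement that scored them, so they check the counting only. Peaks with a regional density common to both lists were not simulated, so the 0 is not an error rate for the real lists. Of 200 simulated lists of 300 long genes with no excess, 5% lay outside the central 95% with span matching and 38% without it. With 15 genes added, 96.5% lay above. Lists of short genes or of clustered genes were not simulated, so the 5% is not an error rate for such families. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.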

Results

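Ipr1, the mouse protein encoded by Sp110 and named for its part in resistance to intracellular bacteria, was mapped on chromatin in RAW264.7 cells, a BALB/c macrophage line. The cells carried a lentiviral construct for Ipr1 with a Flag tag and a biotin acceptor peptide, together with the biotin ligase BirA. Control cells carried the tag and BirA without Ipr1. Chromatin was isolated either with streptavidin, which binds the biotinylated tag, or through the Flag tag. The study comprised 4 libraries, 1 per arm, so no difference has a replicate check. The control of the anti-Flag isolation is titled IgG, while its antibody label reads anti-Flag, and it is called the IgG-titled control here. If it was an IgG isolation, the anti-Flag peaks reflect a difference of antibody as well as of cells. The question addressed was where in the genome tagged Ipr1 is found, and whether both isolations place it at the same sites.

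Streptavidin isolation gave 8628 peaks over its control, and anti-Flag isolation gave 12251. Most streptavidin and anti-Flag peaks rested on few sequenced tags. The median streptavidin peak held 7 tags (quartiles 6 and 7) with a summit height of 5 overlapping tags. The median anti-Flag peak held 5 tags (quartiles 5 and 6) with a summit height of 4. Peaks with 8 tags or fewer made up 89.1% of the streptavidin list and 96.8% of the anti-Flag list. The streptavidin peaks covered 4.89 Mb and held 61404 tags, and the anti-Flag peaks covered 6.70 Mb and held 74079 tags. The library totals are not given in the sources used here, so depth outside the peaks is unknown.

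Scores in both lists lay close to their lower limit. The authors' own score, which is 10 times the negative log10 of the peak p, had a median of 34.3 in the streptavidin list and 33.95 in the anti-Flag list, and no peak of either list scored below 30. A score of at least 50 was reached by 229 streptavidin peaks (2.65%) and 350 anti-Flag peaks (2.86%). No streptavidin peak and 6 anti-Flag peaks reached 100. The authors' fold enrichment had a median of 7.72 in the streptavidin list and 9.24 in the anti-Flag list. Their false discovery rate had a median of 5.48% (highest 9.21%) for streptavidin and 0.02% (highest 0.11%) for anti-Flag. At a rate of at most 5%, 3599 streptavidin peaks and all 12251 anti-Flag peaks remained.

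The highest-scored streptavidin peaks fell mainly within long genes or far from any gene. The first lay in an intron of Sycp1, a synaptonemal complex gene (chromosome 3, 102822330 to 102823529, mm10, score 95.66, 19 tags, 13.1-fold). The second and the third lay within Cdh12, a cadherin gene on chromosome 15 (20601866 to 20603171, score 81.86), and in an intron of Fstl5 on chromosome 3 (76271900 to 76273175, score 81.58). Introns of Nbas, of the DNA repair gene Rad51b and of the dynamin gene Dnm3 held others among the first 15. Olfr112, an olfactory receptor gene, had a peak 1.41 kb from its end, and Ifi202b, an interferon-inducible gene, had one at 7.40 kb. The remaining peaks of this group had Gm21083, Igsf3, Actl9, Lgr5, 4921504A21Rik, Edem1 and D830032E09Rik as their nearest genes, at distances from 9.69 to 499.9 kb.

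The highest-scored anti-Flag peaks lay in short stretches of very high tag count. Of the first 8, 3 lay on chromosome 2 between 98661836 and 98667484, 1031 to 1035 kb from the nearest gene, Lrrc4c. The strongest of them scored 873.87 with 689 tags, with a fold enrichment of 4.57. The next, on chromosome 9 (35304913 to 35305743, 261 tags, 5.42-fold), was 19.98 kb from 4933422A05Rik. A pair near Mir101c on chromosome 9 (from 3021931 and from 3024615) held 147 and 276 tags, and 2 others lay on mitochondrial DNA. The other 7 included introns of Serinc5 (chromosome 13, 92649451 to 92649917, 9 tags, 21.7-fold) and of the neural adhesion gene Chl1 (74 tags, 3.79-fold). Pak3, Gm30853, Gm36851 and Sorcs3 were the nearest genes of 4 others, at 35.3 to 622.3 kb. Olfr1240 was 0.534 kb from the last. The streptavidin list also held a peak at the strongest anti-Flag site on chromosome 2, with 737 tags but a score of 32.46 and a fold enrichment of 2.5. It held another at the chromosome 9 site near 4933422A05Rik (302 tags, score 33.37, 3.43-fold). High tag counts at these sites were therefore not particular to the anti-Flag isolation. No value here separates these sites from places that gather tags in any library of these cells, so their rank does not mark them as Ipr1 sites.

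Few peaks lay at promoters. A summit within 1 kb of a transcription start site (TSS) was found for 71 of 8627 streptavidin peaks on the autosomes and X (0.823%, 95% Wilson interval 0.653 to 1.04%) and for 125 of 12248 anti-Flag peaks (1.02%, 0.857 to 1.21%). More lay near the other end of the same transcripts, with 139 streptavidin summits (1.61%) and 187 anti-Flag summits (1.53%) within 1 kb of a 3' end. Summits were fewer at the TSS and more at the 3' end than in the flanks. Per 0.5 kb there were means of 17.8 streptavidin and 31.2 anti-Flag summits within 1 kb of a TSS, against 26.4 and 40.2 from 1 to 5 kb. Within 1 kb of a 3' end the means were 34.8 and 46.8, against 26.1 and 38.8. In the first 0.5 kb downstream of a TSS there were 8 streptavidin and 14 anti-Flag summits, against 25 and 46 in the 0.5 kb upstream of it. Of the counts within 1 kb of both kinds of end added together, the TSS had 33.8% for streptavidin (27.8 to 40.4%) and 40.1% for anti-Flag (34.8 to 45.6%). A summit near both kinds of end enters both counts, which draws this share toward an even one, and the intervals do not allow for it. Between 1 and 5 kb from the ends these shares were 50.2% and 50.9%, and over the whole 10 kb the anti-Flag share was 50.1%. Intervals cover counting error only, here and throughout.

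**Figure D1:**
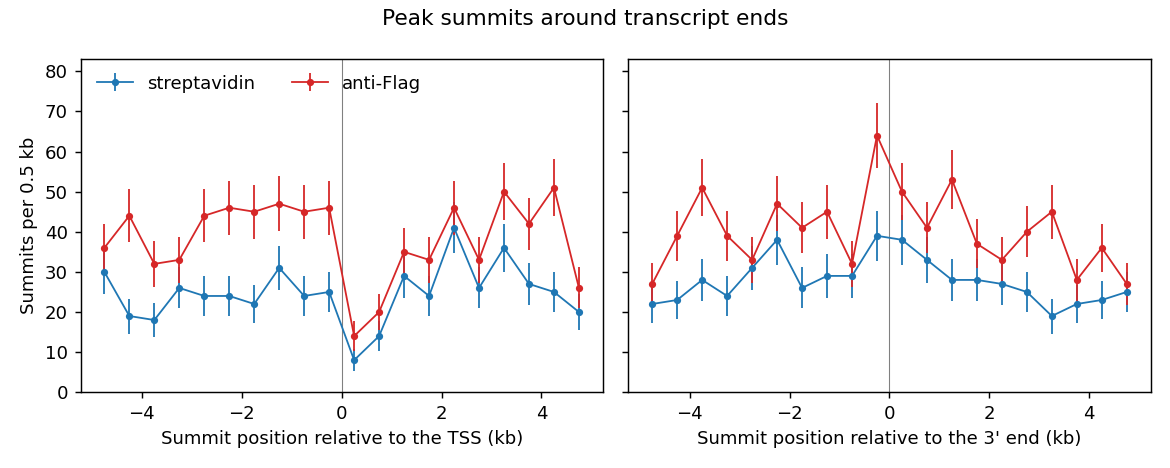
Number of peak summits per 0.5 kb (y axis) by position relative to the nearest TSS (left) or 3' end (right) in kb, for streptavidin (blue) and anti-Flag (red), with negative positions upstream. Bars are the square root of each count, and both lists have their fewest summits in the first 0.5 kb downstream of the TSS (8 and 14).

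Gene ends and gene bodies held fewer summits than random positions on the same chromosomes. A summit within 1 kb of either end of a gene was found for 2.62% of streptavidin peaks (2.30 to 2.98%), against a mean of 3.43% (3.05 to 3.84%) over 1000 random placements. For anti-Flag the share was 2.69% (2.41 to 2.99%) against 3.47% (3.17 to 3.80%). Gene bodies held 38.4% of streptavidin summits (37.4 to 39.5%), against 41.9% (40.8 to 42.9%) by placement, and 40.1% of anti-Flag summits (39.3 to 41.0%), against 42.0% (41.2 to 43.0%). Every one of the 1000 placements gave a higher share than observed in these 4 comparisons. Placements also fall on sequence to which no tag can be assigned, which was not modelled.

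By the authors' deposited table, 5206 streptavidin peaks (60.3%, 59.3 to 61.4%) and 7106 anti-Flag peaks (58.0%, 57.1 to 58.9%) had no gene feature. Introns without an exon were the most frequent feature in the authors' deposited table, with 2637 streptavidin peaks (30.6%) and 3906 anti-Flag peaks (31.9%). Exons were touched by 369 streptavidin peaks (4.28%) and 572 anti-Flag peaks (4.67%) in the authors' deposited table. Among them, 5' untranslated regions were touched by 31 and 41 peaks, and 3' untranslated regions by 107 and 151, in the authors' deposited table. Promoters as marked in the authors' deposited table were touched by 282 streptavidin peaks (3.27%) and 494 anti-Flag peaks (4.03%). The flanks of 3' ends were touched by 324 (3.76%) and 483 (3.94%). These promoter marks reach beyond 1 kb, as for the streptavidin summit 4246 bp from the TSS of Olfr1406. The authors' deposited table named 2445 genes for streptavidin and 3500 for anti-Flag.

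Olfactory receptor genes, a family expressed mainly in the nose, had more peaks than other genes of their span classes in both lists. A summit within 5 kb of a TSS was found for 74 of 1111 olfactory receptor genes in the streptavidin list (6.66%, 5.34 to 8.28%; mean of random lists 25.8) and for 92 in the anti-Flag list (8.28%, 6.80 to 10.0%; mean 40.7). Both counts were above all 10000 random lists of the same size and gene span. They stayed above all 1000 draws in which peaks were moved by 5 to 500 kb and genes were counted at either end (85 genes against a mean of 61.5 for streptavidin, 104 against 77.9 for anti-Flag). Random lists matched on peaks within 1 Mb as well as on gene span (matching on peak density) had higher means. At the TSS these means were 48.4 for streptavidin and 61.0 for anti-Flag (percentile 100 in both). At either reference end they were 64.3 and 80.2 (percentiles 99.99 and 99.96). The excess was therefore smaller with this matching than with gene span alone, but the call was kept. At a score of at least 50 the streptavidin call ended (percentile 93.7), with only 2 genes against a random mean of 0.623. The anti-Flag call was kept there (percentile 99.88). Olfr917 and Olfr918 shared 1 streptavidin peak (chromosome 9, 38668859 to 38669550, score 57.25), and Olfr397 and Olfr417 had scores of 45.32 and 44.92. In the anti-Flag list Olfr1240 (72.93), Olfr703 (53.1), Olfr1121 (52.13) and Olfr670 (50.77) led the family.

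Vomeronasal receptor genes, which encode pheromone receptors, stood just above the random lists, with 13 of 353 for streptavidin (mean 7.33, percentile 97.6) and 20 for anti-Flag (mean 12.9, percentile 97.54). Vmn2r115, Vmn1r235, Vmn1r233 and Vmn1r80 had the highest-scored streptavidin peaks of this group, from 51.58 down to 38.96. Vmn1r21, Vmn2r77, Vmn1r25 and Vmn1r52 had the highest-scored anti-Flag peaks, from 48.17 down to 39.08. With genes tied to any summit within 50 kb, this family fell to percentiles 7.90 and 23.7. Genes taken from the authors' annotation (72.7 and 90.9) or counted at either reference end (90.1 and 96.8) also ended the call. With genes counted at either reference end, the percentiles were 61.7 and 95.2 against peaks placed at random, and 95.7 and 99.9 against peaks moved by 5 to 500 kb. A score of at least 50 ended the streptavidin call (90.7). Matching on peak density kept the call at the TSS (99.7 and 99.6) and at either reference end (97.53 and 99.6).

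MicroRNA genes had fewer peaks than other genes of their length, with 14 of 1190 for streptavidin (1.18%; mean of random lists 28.1, percentile 0.01) and 20 for anti-Flag (1.68%; mean 53.0, below all lists). Mir31, Mir331, Mir680-3 and Mir804 led the streptavidin members, with scores from 38.56 down to 37.13. Mir3098, Mir3471-1, Mir101c and Mir1224 led the anti-Flag members, from 44.46 down to 38.21. The Mir101c peak held 134 tags with a fold enrichment of 4.26, near the high-count pair on chromosome 9 described above. The authors' transcripts place Mir680-3, Mir3098 and Mir3471-1 elsewhere than the reference does. The call ended when peaks were moved by 5 to 500 kb and genes counted at either reference end (percentiles 13.1 and 36.9). For streptavidin it also ended with genes from the authors' annotation (18.3). It was kept at either reference end against span-matched lists (19 against 34.7, percentile 0.015, and 34 against 66.5, below all lists), with density matching there (0.83 and 0.16), and against peaks placed at random (0.70 and 2.0). Of microRNA genes with a summit within 5 kb of either end, the authors' deposited table held 57.9% for streptavidin and 47.1% for anti-Flag, against 86.4% and 86.7% of all genes.

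The lists tied to macrophage biology lay inside the central 95% of random lists when summits within 5 kb of a TSS were counted, where random means of 0.327 to 1.37 are too low for a lower count to show. Interferon response genes had 0 of 50 members with a streptavidin summit within 5 kb of a TSS and 1 with an anti-Flag summit, Ifi35 (score 31.57), at percentiles 20.8 and 42.4. Genes of NF-kB and inflammatory cytokines had 1 member of 38 for streptavidin, the kinase gene Ikbkb (33.79), and 0 for anti-Flag. Pyroptosis and necroptosis genes had 1 of 18 for streptavidin, Casp4 (36.29), and 2 for anti-Flag, the necroptosis effector gene Mlkl (38.78) and the DNA sensor gene Aim2 (30.06), at percentiles 83.9 and 94.0. Apoptosis genes had Bcl2l1 (30.5) for streptavidin and 0 for anti-Flag among 45. Toll-like receptor signalling had 0 and 1 of 29, the latter being Ly96 (40.64), and macrophage markers had 0 and 1 of 35, the latter being the scavenger receptor gene Cd36 (30.8). Lysosome and phagosome genes had Atp6v0a1 (38.27) for streptavidin and 0 for anti-Flag among 39. Autophagy (30 genes), antigen presentation (24) and oxidative phosphorylation (31) had 0 in both lists. With genes from the authors' annotation, macrophage markers had 0 of 35 for streptavidin (random mean 3.85, percentile 0.46) and NF-kB and cytokine genes 0 of 38 for anti-Flag (mean 3.20, percentile 1.39). With summits within 50 kb, antigen presentation had 0 of 24 (mean 5.41, percentile 0.07) and apoptosis 5 of 45 (mean 10.4, percentile 2.27) for streptavidin. In the other isolation these 4 lists lay inside the central 95% under the same setting.

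The SP family and PML bodies had 2 of 18 members in the streptavidin list, Pml (42.12), which encodes the scaffold of nuclear PML bodies, and Trim24 (30.59), at percentile 97.3, and 0 in the anti-Flag list. With matching on peak density as well, the SP family was just above the central 95% for streptavidin (percentile 97.7). It was inside at either reference end (88.2, and 89.0 with that matching), by the authors' annotation (67.1) and within 50 kb (31.4). DNA replication and cell cycle genes had 0 of 42 for streptavidin and 3 for anti-Flag, Mki67 (38.04), Ccne2 (37.32) and Myc (34.09), at percentile 93.3. MAPK signalling had Atf2 (37.55) for streptavidin and 0 for anti-Flag among 34, and with genes from the authors' annotation they lay below the central 95% for anti-Flag (2, mean 5.999, percentile 1.93). Ribosomal protein genes had 0 of 81 for streptavidin and 3 for anti-Flag, Rpl3 (38.81), Rpl37 (32.61) and Rpl27 (31.57), and within 50 kb they lay below the central 95% for streptavidin (9, mean 16.3, percentile 1.49). Zfp zinc finger genes had 2 of 368 for streptavidin, Zfp451 and Zfp352 (percentile 3.02, 1.19 without matching, 7.17 with matching on peak density and 27.8 at either reference end), and 7 for anti-Flag, led by Zfp521 (42.23), Zfp142, Zfp677 and Zfp462 (percentile 14.7). The histone pattern matched 2 genes, and neither had a peak. Of markers of other cell types, T cell markers had 1 anti-Flag member of 22, Cd28 (31.43), and hepatocyte markers had 2 of 22, Ahsg (54.62) and Cyp3a11 (43.73), at percentile 93.3. Hepatocyte markers lay above the central 95% for anti-Flag within 50 kb (12 of 22, mean 6.69, percentile 99.1), at either reference end within 5 kb (4, mean 1.22, percentile 97.98) and at a score of at least 50 (1, mean 0.0136, percentile 99.3). With matching on peak density they lay inside it, both at the TSS (89.1) and at either reference end (95.6). B cell (16), neuron (25) and muscle (22) markers had 0 in both lists. Over 25 lists, 3 lay outside the central 95% for each isolation, where independent lists with continuous percentiles would give 1.25. That number is a rough guide only, since lists with low random means cannot rank below the band. Percentiles of families whose neighbouring genes share a peak are in turn more extreme.

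**Figure D2:**
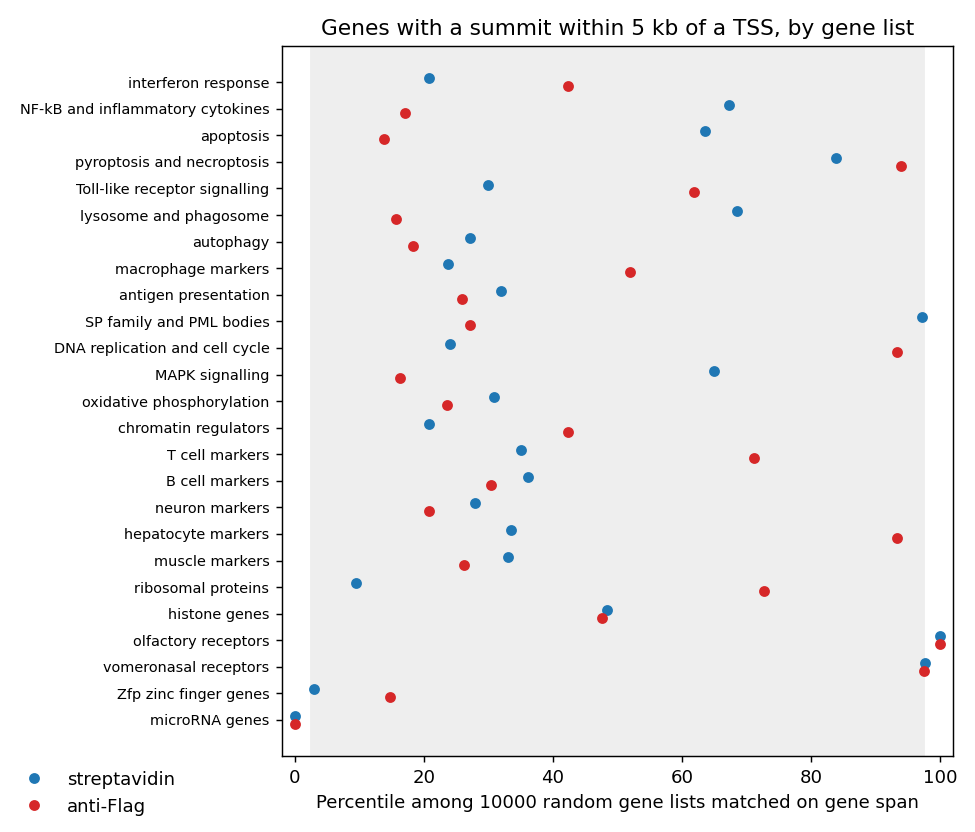
Percentile of each gene list's count of genes with a summit within 5 kb of a TSS, among 10000 random lists matched on gene span, for streptavidin (blue) and anti-Flag (red). The shaded band is the central 95%. Olfactory and vomeronasal receptor genes lie above it and microRNA genes below it in both lists.

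Peaks were spread unevenly over the chromosomes, and in a similar way in both lists. Chromosome 3 had the highest density, with 952 streptavidin peaks (5.95 per Mb, 95% exact Poisson interval 5.58 to 6.34) and 1065 anti-Flag peaks (6.66 per Mb, 6.27 to 7.07). These were 1.76 and 1.37 times the median of the other autosomes, which was 3.37 and 4.84 per Mb. Chromosome X had the lowest density, with 42 streptavidin peaks (0.246 per Mb, 0.177 to 0.333) and 117 anti-Flag peaks (0.686 per Mb, 0.567 to 0.822). Chromosomes 7 and 11, with 2312 and 1938 genes, were the lowest autosomes for both isolations, with 2.48 and 2.44 per Mb for streptavidin and 3.40 and 4.003 for anti-Flag.

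**Figure D3:**
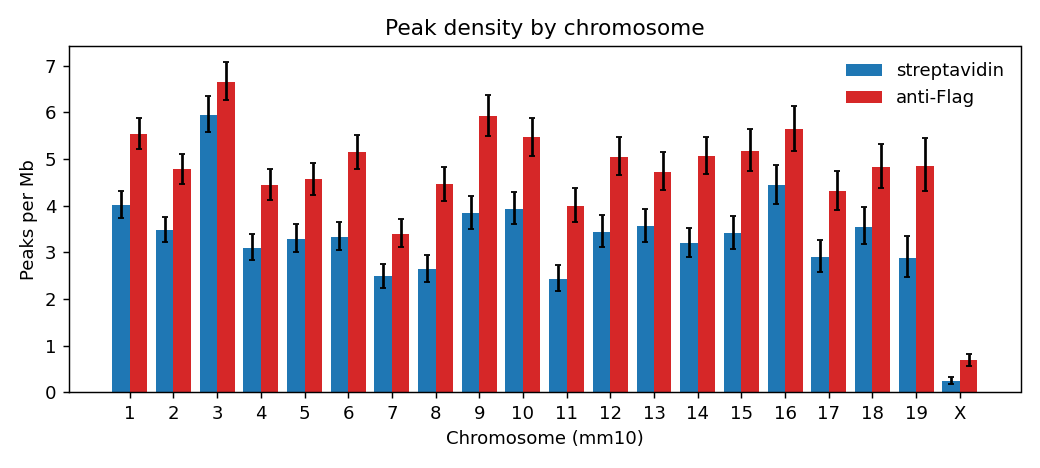
Peaks per Mb of chromosome (y axis) for chromosomes 1 to 19 and X (x axis), for streptavidin (blue) and anti-Flag (red), with exact 95% Poisson intervals. Chromosome 3 is highest in both lists (5.95 and 6.66 per Mb) and X lowest (0.246 and 0.686).

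On chromosome 3 every 5 Mb segment from 73 to 123 Mb was above the median of both lists, with 27 to 76 streptavidin and 30 to 58 anti-Flag peaks. The segment from 108 to 113 Mb held 76 streptavidin and 58 anti-Flag peaks, against medians of 17 and 25 per segment over the autosomes. The segment from 113 to 118 Mb held 62 and 49, and that from 73 to 78 Mb held 61 and 44. These segments were chosen after their values were seen. Over 472 such segments, the densities of both lists were correlated within chromosomes (Pearson r = 0.701, Spearman rho = 0.726), where circular shifts of one list along each chromosome gave r from -0.143 to 0.0974 in the central 95% of 1000 draws. Without chromosome 3 the value was 0.720. This correlation is across segments, which are not independent replicates. Segments with more genes had fewer peaks. Genes were counted at their lower coordinate. In 1 Mb segments with 0 genes there were 5.57 streptavidin and 7.24 anti-Flag peaks per Mb, and in segments with 16 or more genes 2.24 and 3.29.

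**Figure D4:**
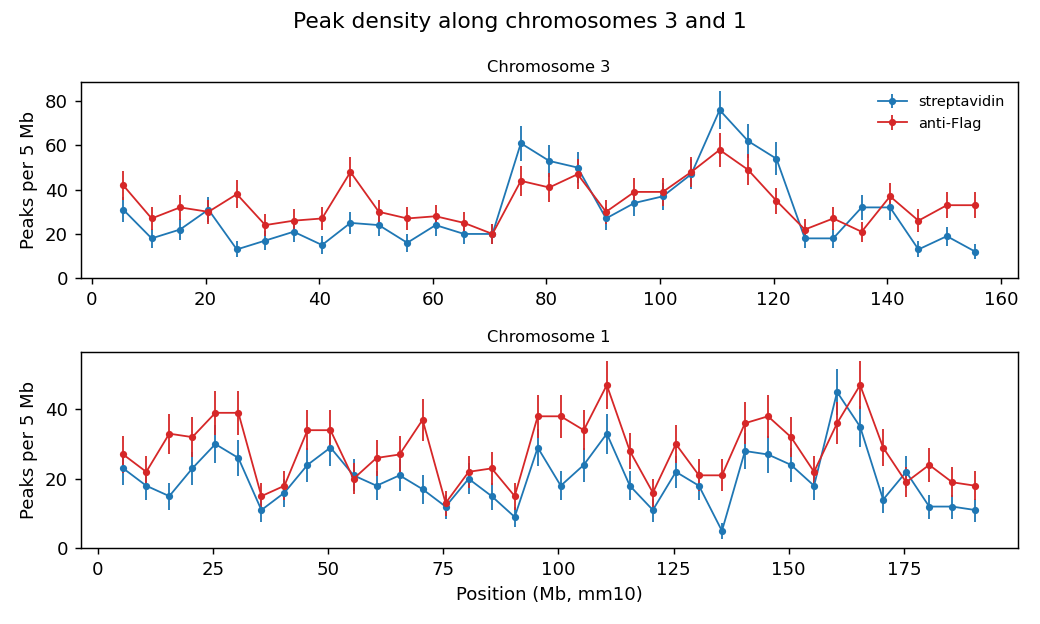
Peaks per 5 Mb segment (y axis) along chromosomes 3 (top) and 1 (bottom) in Mb, for streptavidin (blue) and anti-Flag (red), with bars at the square root of each count. On chromosome 3 both lists stay above their medians of 17 and 25 from 73 to 123 Mb, reaching 76 and 58 peaks.

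The isolations shared few peaks. Of 8627 streptavidin peaks, 124 (1.44%, 1.21 to 1.71%) had at least 1 bp in common with an anti-Flag peak, and these met 124 of 12248 anti-Flag peaks (1.01%, 0.850 to 1.21%). Random placement of the streptavidin peaks gave a mean of 48.9 shared peaks (central 95% 36 to 63, highest of 1000 draws 75), so the observed number was 2.54 times the mean (Poisson interval 2.11 to 3.02). When each peak was moved by only 5 to 500 kb, the mean was 59.1 and the ratio 2.10 (1.74 to 2.4997).

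**Figure D5:**
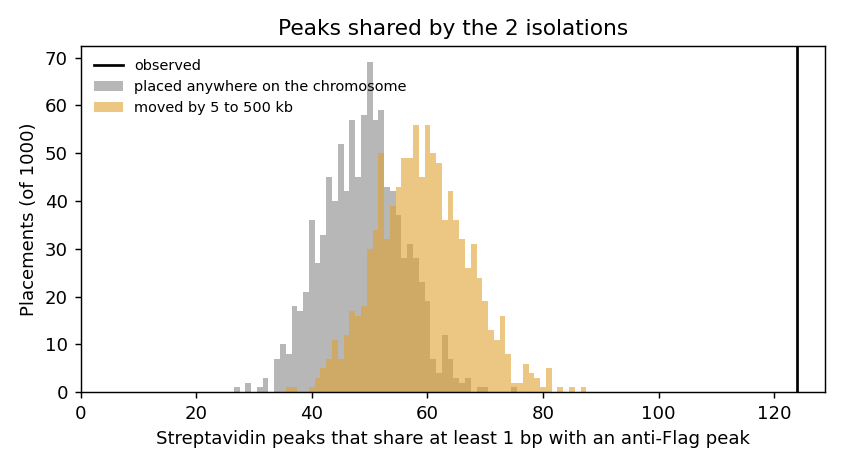
Number of placements out of 1000 (y axis) by the number of streptavidin peaks sharing at least 1 bp with an anti-Flag peak (x axis), for peaks placed anywhere on their chromosome (grey) or moved by 5 to 500 kb (orange). The black line is the observed number, 124, above every placement.

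None of the 124 shared streptavidin peaks had a summit within 1 kb of a TSS, and 7 were within 5 kb, where the shares over all streptavidin peaks would give 1.02 and 7.09. Gene bodies held 46 of them (37.1%, 29.1 to 45.9%). The pair placed first by the worse of its 2 ranks lay within Pcbp3, a gene for an RNA-binding protein, on chromosome 10 (streptavidin 76952288 to 76953271, score 53.72; anti-Flag 76951588 to 76952354, score 52.58). Next came a site 61.0 kb from Slc5a7 on chromosome 17 (45.51 and 54.16) and a site 378.5 kb from Nmbr on chromosome 10 (51.58 and 44.25). Rapgef2 on chromosome 3 was the nearest gene of 2 shared sites, 1 inside it and 1 at 52.3 kb. These sites were chosen after their values were seen.

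Shared peaks scored slightly higher than the rest in the anti-Flag list, and no difference was detectable in the streptavidin list. Their median score was 34.0 in the streptavidin list, against 34.3 for unshared peaks (difference -0.295, bootstrap interval -1.04 to 1.07), and 34.8 in the anti-Flag list, against 33.95 (difference 0.825, 0.179 to 2.13). Their median rank by score, as a percent of the list, was 52.7% against 50.1% for streptavidin and 44.7% against 50.04% for anti-Flag. Fold enrichment had medians of 7.46 and 7.76 for streptavidin (difference -0.300, -0.380 to 0.645), and of 9.06 and 9.26 for anti-Flag (difference -0.200, -0.835 to 0.670).

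By gene, 38 genes had a summit within 5 kb of a TSS in both lists, out of 526 for streptavidin and 829 for anti-Flag. Independent lists of these sizes among 26123 genes would share 16.7, and span-matched random lists shared a mean of 18.0 (central 95% 11 to 27). The observed number was 2.11 times that mean (1.49 to 2.89), and 1.26 times with summits within 50 kb of either gene end. Matching was on gene span alone, so the regional density and the olfactory receptor excess common to both lists were not removed from these ratios. The interval treats genes as independent, although neighbours can share a peak. These ratios alone therefore do not show common sites. The olfactory receptor gene Olfr1406 came first by its lower rank, with upstream peaks scoring 40.71 for streptavidin and 46.75 for anti-Flag. Gm6756, the protease gene Tmprss15, the DNA repair gene Xrcc2 and Sowaha followed. Olfr508, Lipk, Olfr397 and Fbxw7, which encodes a ubiquitin ligase subunit, had peaks of both isolations that overlapped. The streptavidin peak of Fbxw7 lay on chromosome 3 at 84949998 to 84950498 (6 tags) and the anti-Flag peak at 84949389 to 84950290 (11 tags), both intronic. The others of the first 20 were Ralyl, 2610008E11Rik, Ncbp3, Olfr577, Urgcp, 4933413L06Rik, Enpp2, 4930440C22Rik, Capza1, St7l and Mpc2, and in these the peaks of the 2 isolations did not overlap. Capza1 and St7l, which are neighbours, were named through the same peaks.

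No peak of either list lay in Sp110, the gene of Ipr1 itself (chromosome 1, 85570735 to 85610850), or in its neighbours Sp140 and Sp100. The streptavidin peak nearest to Sp110 was 227.3 kb away and the anti-Flag peak 307.6 kb. For Sp140 these distances were 193.1 and 281.9 kb, and for Sp100 they were 128.1 and 217.0 kb.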

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

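The peak moves, the omission of peaks with 20 or more tags, the summit distances, the long genes and the background at gene ends were tests chosen after the lists had been seen, the 2 of segment density after the result they measure was seen, and the one of gene density replaced a first one, the correlation of peaks with gene count (-0.410 and -0.512), which decided nothing.

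Peaks on mitochondrial DNA and chromosome Y, which no comparison used, were in the authors' lists of Ipr1 against control libraries. The streptavidin list had 1 mitochondrial peak (1767 to 3009, 16 tags, 9.33-fold over the caller's background). The anti-Flag list had mitochondrial peaks from 3 to 4622 (127 tags, 6.07-fold) and from 10872 to 15813 (114 tags, 5.13-fold), and 1 peak on chromosome Y (1412076 to 1412594, 5 tags, 10.9-fold). The mitochondrial streptavidin peak overlapped an anti-Flag one, which brought the shared peaks to 125 in all.

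Peaks of the isolations coincided 2.54 times as often as random placement gave. Regional density did not account for all of it, since moving each peak by 5 to 500 kb left a ratio of 2.10 (1.74 to 2.4997). Stretches of very high tag count did not account for it either, since the ratio without peaks of 20 or more tags was 2.42 (2.01 to 2.90). Summits of coinciding peaks lay closer together (median 186 bp) than in placements that coincided by chance (central 95% 203 to 360 bp), as sites common to both isolations would give. Such sites may be places where tagged Ipr1 sits, or places that gather tags in any library of these cells, and unique alignment and the control libraries' own peaks were not analysed here.

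Peak density differed between segments in the same way in both lists, with r = 0.701 over 5 Mb segments against -0.143 to 0.0974 for circular shifts. Gene density alone did not account for it, since the correlation was 0.627 after the gene count was removed (shifts -0.148 to 0.115). Copy number of this cell line, or another regional property, is a candidate explanation that the correlation leaves open, and no value here separates these from Ipr1 binding in the same regions. The same limit holds for chromosome X, whose copy number was not measured here. Densities there were 0.0730 and 0.141 of the median autosome.

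Fewer summits lay within 1 kb of a TSS than within 1 kb of a 3' end, through both fewer at the TSS and more at the 3' end than in the flanks. Short genes and close neighbours did not account for it, since the TSS share of both lists together stayed at 35.3% (27.2 to 44.4%) over genes longer than 20 kb with no other gene within 5 kb, although the interval of anti-Flag alone (41.5%, 30.4 to 53.7%) includes an even share. A higher local background at the TSS was predicted to lower the share of peaks held at the genome-wide background. That share was higher at the TSS (67.9%) than at 3' ends (62.9%), but the difference of 4.97 percentage points has an interval (-3.41 to 13.4) that leaves this open. Base composition, which could lower coverage at promoters, was not analysed here, and no biological explanation was tested.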

How the results depend on the processing

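Score limits of 50, wider windows and long genes for the TSS part of gene ends, peak moves, matching on peak density, the omission of chromosome 3 or of peaks with 20 or more tags, and gene ends from the reference were chosen after the data had been seen. Streptavidin fell to 3599 peaks at 5% false discovery, 822 at 10-fold, 229 at score 50 and 0 at score 100, and anti-Flag to 5462, 350 and 6 at the last 3, with 12251 at 5%. Shares near a TSS rose to 5.71% and 6.27% within 5 kb and 9.35% and 10.4% within 10 kb. At score 50 they were 1.32% and 0.287%, with gene body shares of 35.1% and 34.8%, and at score 100 both anti-Flag shares were 0%. The TSS part of the added counts near gene ends was 47.0% and 48.7% within 5 kb, and 48.6% and 50.1% within 10 kb, where the anti-Flag share was even (48.2 to 52.1%). Summits near both kinds of end, which enter both counts, draw these shares toward an even one. It was 27.5% for streptavidin in long genes without neighbours and 20% for anti-Flag at score 50 (1 summit against 4). Streptavidin had 5 lists outside the central 95% with summits within 50 kb and 0 at score 50, against 3. Vomeronasal receptors lost their call within 50 kb (percentiles 7.90 and 23.7) and, for anti-Flag, at score 50 (36.9; 0 genes against 0.301 expected), with no lower count shown. Per gene, chromosome 3 stood at 2.22 and 1.66 times the median autosome. Shared peaks were 3.24 times placement with half-length overlap, 3.71 with summits within 200 bp, 2.10 when moved and 2.01 when moved without peaks of 20 or more tags. Shared genes were 1.39 times the random mean by the authors' genes and 1.26 within 50 kb. Wider windows and stricter limits change counts of peaks and genes by construction. Why the shares, percentiles and ratios moved was not tested.

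Of 57 settings for the main results, 24 left the value within its counting interval or within 1.5 times the count. For the 3 gene families outside the central 95%, 37 settings kept the call and the others ended it, 14 with the percentile on the same side of the middle and 3 with it on the other. No streptavidin result but the number of peaks could be given at score 100, nor gene lists or sharing for anti-Flag there. At score 50 sharing gave no usable value, with 1 shared peak against 0.042 expected and 0 shared genes against 0.012; these were first computed and then left out as too few. No paired analysis was possible because each arm has 1 library. Peaks of 5 to 7 tags limit what any of these lists can resolve.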
